A study of Mus musculus with 10 samples.

How the data were processed

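Neural stem cells from the ventral midbrain of ICR mouse embryos at embryonic day 10 carried a lentivirus for Lin28a or a mock control. They were grown in culture with a passage every 4 days and sampled at passage 1 (P1) and passage 3 (P3). The 10 libraries comprised 4 of RNA-seq, 4 of small RNA and 2 of polysome RNA at P3 (polysome-seq). Each combination of assay, virus and passage was 1 group with 1 library, taken from the sample titles. There were no replicates, so no test was run and no p-value or SD across samples was computed. Every difference below describes these libraries.

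The RNA-seq values were deposited as 1 FPKM value (fragments scaled to gene length and library size) for each RefSeq gene. Bowtie 1.0.0, TopHat2 2.0.6, Cufflinks 2.1.1 and genome build mm9 were named for these libraries per the submitters' processing notes, which do not say which step used which tool. The file headers do not name the unit. It was taken from the named tools and from the values, and genes with no estimate are all listed at a floor of 4.8e-07. The polysome values were deposited by the authors in the same gene layout and are read here as RPKM (reads scaled in the same way), since low genes step in whole reads. Their floors are 0.00204 for control and 0.00331 for Lin28a, so the polysome libraries were counted in another way than the RNA-seq libraries. The gradient fractions that were sequenced are not given in the sources used here. The sample descriptions call the RNA-seq and polysome libraries poly(A)-selected, while the extraction text names a total RNA kit. RNAs without a poly(A) tail were high in the polysome libraries, so levels of a gene in the 2 assays are given side by side as values only. Lists were set against random lists matched on RNA level, and for 1 list its members were also counted against the median of all genes. The small RNA values are read counts on each mature microRNA, per the file headers, deposited without normalization. A microRNA encoded at several loci may be counted more than once, so levels of different microRNAs are not comparable, while ratios between libraries are. A second deposited column, counts on the primary hairpin, was not used.

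The tables held 17919 genes, of which 16802 symbols matched a reference name table for assembly GRCm38. That table served for names alone, and no coordinates are printed because the builds differ. All per-sample columns belonged to the 10 libraries, and 0 columns of other samples were found. The total depth of the RNA-seq and polysome libraries is unknown. The steps between low values gave relative depth only. The P1 Lin28a library was 1.15 times as deep as the P1 control library, from 244 of 1325 low genes at the most frequent ratio. The P3 control and P3 Lin28a libraries were 1.01 and 1.03 times as deep as P1 control, from 75 of 960 and 139 of 1000 genes. The polysome Lin28a library was 1.04 times as deep as its control, from 241 of 2570 genes.

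Gene values were compared as log2 ratios after a pseudocount of 1 was added, which understates changes of low genes. Genes at 1 or more in at least 1 of the 2 libraries entered a comparison. Genes past a 2-fold difference on that scale are counted as higher or lower, and counts of smaller differences are marked as by any amount or stand beside the count past 2-fold. The polysome to RNA ratio was the difference between the polysome and the P3 RNA-seq log2 ratios, for genes at 5 or more in all 4 libraries. MicroRNA counts were scaled to CPM, counts relative to all microRNA counts of the library,, and microRNAs at 10 CPM or more in at least 1 of the 2 libraries were compared with the same pseudocount. Ratios of microRNA counts are given with exact conditional binomial intervals at 95%. Intervals and floors cover counting error only, those of microRNAs with several loci may be too narrow, and 3 reads set the floor for an undetected microRNA. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

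The comparisons, the 35 gene lists, the 10 microRNA lists and the alternatives were fixed before the data were examined. Each list is described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, drawn for each gene from the 200 genes nearest in mean expression (40 for microRNAs). A median outside the middle 95% of the random medians is called above or below the random range, as a description of these libraries. A list of genes with let-7 sites in the 3' untranslated region was planned but needed sequences not used here. The genes named are Lin28a and Lin28b, up to 4 members of each list with the largest ratios, and the 10 highest and 10 lowest genes. For pairs of comparisons these were ranked by the smaller ratio of the 2 among genes past 2-fold the same way in both, or opposite ways for passage against polysome. For microRNAs the rule took each let-7 and miR-98 guide strand, up to 4 members per list and the 10 highest and lowest shared between comparisons. Genes without a symbol and short non-coding genes were left out of these rankings. A few further genes are named as chosen after their values were seen. Some genes that the rule names are not reported here.

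The passage comparison in control and the Lin28a comparison at P3 share the P3 control RNA-seq library. Unchanged groups sharing that library were therefore simulated with 200000 genes and a noise SD of 0.187 per library. That SD was derived from the spread of the Lin28a to control ratios at P1. The alternatives were a pseudocount of 0.1, minimum values of 5 or no minimum, centring on the median gene, upper quartile scaling, minimums of 1 or 10 for the polysome to RNA ratio, and, for small RNA, scaling without the let-7 family, centring, a minimum of 100 CPM and no minimum.

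The procedure was tested on simulated data built on P1 RNA-seq values. With no replicates to estimate noise between cultures, the simulated noise was assumed. Of 200 genes changed 3-fold among 12489, 199 were called with 0 false calls. Of 200 genes changed 1.5-fold among 12477, 0 passed the 2-fold limit. All 50 changed lists lay above the random range (100%) at both sizes. Of 200 unchanged lists, 8.5% lay outside the middle 95% in the 3-fold simulation and 4% in the 1.5-fold one. These calls and percentages hold for the assumed noise only and are not error rates for the deposited libraries. The intervals of microRNA ratios covered the true ratio in 96.2% of 2000 draws.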

Results

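Lin28a is an RNA-binding protein of early embryos and stem cells that blocks the maturation of let-7 microRNAs. The libraries address how its overexpression changes RNA in ventral midbrain neural stem cells, a source of midbrain dopamine neurons, as they are passaged. RNA-seq and small RNA libraries covered control and Lin28a cultures at P1 and P3. Polysome-seq, the sequencing of RNA bound to several ribosomes, covered control and Lin28a at P3. Each group held 1 library, so no difference below has a replicate check. Between 12338 and 12461 of 17919 genes reached an FPKM of 1 in each RNA-seq library, and 12028 and 12098 genes reached an RPKM of 1 in the polysome libraries of control and Lin28a. The small RNA libraries held 6322534 microRNA counts in P1 control, 8288085 in P3 control, 8288819 in P1 Lin28a and 8542827 in P3 Lin28a. In these 4 libraries 1209 microRNAs were seen, 764 of them in all 4. Across genes, the log2 values of control and Lin28a correlated at a Pearson r of 0.994 at P1 and 0.986 at P3, while P1 and P3 correlated at 0.936 in control and 0.958 in Lin28a. Genes are not independent replicates, and these correlations are descriptive.

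The Lin28a transcript followed the labels in all 6 libraries. Lin28a (NM_145833) was at 0.128 FPKM in P1 control and 0.0620 in P3 control, against 478 in P1 Lin28a and 104 in P3 Lin28a. In polysome-seq it was listed at the floor in control and reached 17.9 RPKM in Lin28a. Its level in the Lin28a culture was thus lower at P3 than at P1, with a log2 ratio of -2.19. The paralog Lin28b (NM_001031772) stayed under 1 in every library, with 0.725 FPKM in P1 control, 0.273 in P3 control, 0.762 in P1 Lin28a, 0.115 in P3 Lin28a, and 0.570 and 0.515 RPKM in the polysome libraries of control and Lin28a.

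Passaging without Lin28a went with lower neuronal and midbrain patterning genes and higher glial genes. Of 28 measured pan-neuronal genes, 25 were lower at P3 and none was higher past 2-fold, with a median log2 ratio of -2.43. They included the neurogenic factor Nhlh2 (-4.66), the neuronal tubulin Tubb3 (-3.96) and Neurod1 (-3.65). Of 23 ventral midbrain and floor plate genes 19 were lower (median -2.09), with the morphogen Shh at -3.82, the axon guidance gene Slit2 at -3.65 and Foxa2 at -3.40. Of 14 genes of midbrain dopamine neurons 10 were lower (median -1.51), among them Lmx1b (-2.81) and Dlk1 (-2.67). Oligodendrocyte genes were higher in 18 of 19 cases, with a median of 3.56, among them the myelin gene Mbp (6.88) and the precursor gene Gpr17 (6.09). Astroglial genes were higher in 20 of 29 cases (median 2.03), with Gfap at 6.36, Apoe at 5.79, Aqp4 at 4.49 and S100b at 4.46.

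Metabolic and proliferation genes also differed between P1 and P3 in control. All 22 glycolysis genes were higher at P3, 20 of them past 2-fold (median 1.83), among them Aldoc (3.19), Gpi1 (3.04) and Pgk1 (2.65). All 76 oxidative phosphorylation genes were higher, but only 6 past 2-fold (median 0.69). Antioxidant genes were higher past 2-fold in 11 of 32 cases (median 0.63), led by the metallothioneins Mt2 (4.67) and Mt1 (4.07). All 40 cell cycle genes were lower, 13 past 2-fold (median -0.82), with Mcm2 at -1.61 and Ccne2 at -1.60. Of 29 genes of cell cycle inhibition and the p53 response 12 were higher (median 0.66), with Cdkn2b at 3.46, Fas at 2.58 and Cdkn1a at 2.07. Genes known as let-7 targets were lower past 2-fold in 9 of 27 cases (median -0.60), among them Igf2bp1 (-2.18), Mycn (-1.99) and Ccnd2 (-1.71). In total 1496 genes were higher and 1059 lower at P3 among 13011. All these list medians lay outside the random range.

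The Lin28a culture moved along many of the same lines from P1 to P3. Oligodendrocyte genes were higher past 2-fold in 17 of 18 cases (median 3.44), astroglial genes in 21 of 29 (median 1.76) and glycolysis genes in 19 of 22 (median 2.17). Mbp was at 6.39, Gpr17 at 5.67 and the hypoxia-responsive kinase Pdk1 at 3.35. Neuronal genes were lower in 19 of 28 cases, with a median of -1.14 that compares with -2.43 in control. Ventral midbrain genes were lower in 17 of 24 cases (median -1.21), with Wnt1 at -3.11 and Shh at -2.68, and 7 of 14 dopamine neuron genes were lower (median -0.88). Cell cycle genes had a median of -0.37 with 13 of 40 lower, oxidative phosphorylation genes 0.47 with 1 of 76 higher, antioxidant genes 0.35 with 5 of 32 higher, p53 response genes 0.72 with 11 of 29 higher, and let-7 targets -0.40 with 6 of 27 lower. In total 1077 genes were higher and 617 lower at P3 among 12850.

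Across 12723 genes the passage ratios of the 2 cultures correlated at a Pearson r of 0.905 and a Spearman rho of 0.897, with no library in common. Both cultures had 935 genes higher and 518 lower at P3, where independent lists would share 122 and 49.8. The genes highest at P3 in both included the angiotensin precursor Agt (7.82 in control, 6.43 in Lin28a), Mbp, Gpr17, Bcas1 (5.54, 5.58), the glial factor Sox10 (5.22, 5.57), Apoe, the myelin enzyme Cnp (4.58, 4.64), Ndufa4l2 (4.53, 5.49) and Cldn11 (4.86, 4.50). The lowest included the growth factor Fgf15 (-4.29, -4.43), the progenitor factor Dbx1 (-5.05, -3.75), the Wnt ligands Wnt8b (-3.69, -3.22) and Wnt1 (-2.75, -3.11), Islr2 (-5.04, -3.07), E030019B13Rik (-3.35, -3.06), the Wnt antagonists Dkk2 (-2.97, -2.98) and Wif1 (-3.77, -2.81), and somatostatin, Sst (-2.88, -2.95).

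Markers of other cell types gave few measured genes. Endothelial genes were measured for 4 of 17 members in the passage comparisons, with Flt1 at 2.07 in control, and their medians (0.79 in control, 0.63 in Lin28a) lay inside the random range. Microglial genes were measured for 2 of 20, Lyz2 (-1.45 in control) and Cd68 (0.59). Of 18 mesenchymal and fibroblast genes 6 were higher and 7 lower in control (median -0.21) and 6 higher and 4 lower in Lin28a (median -0.22), both inside the range. The neural crest and Schwann cell list had 3 measured genes, with medians of 5.22 in control and 5.44 in Lin28a. Sox10, which is also on the oligodendrocyte list, was among them, and Mitf was at 0.63 and 0.66.

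**Figure D1:**
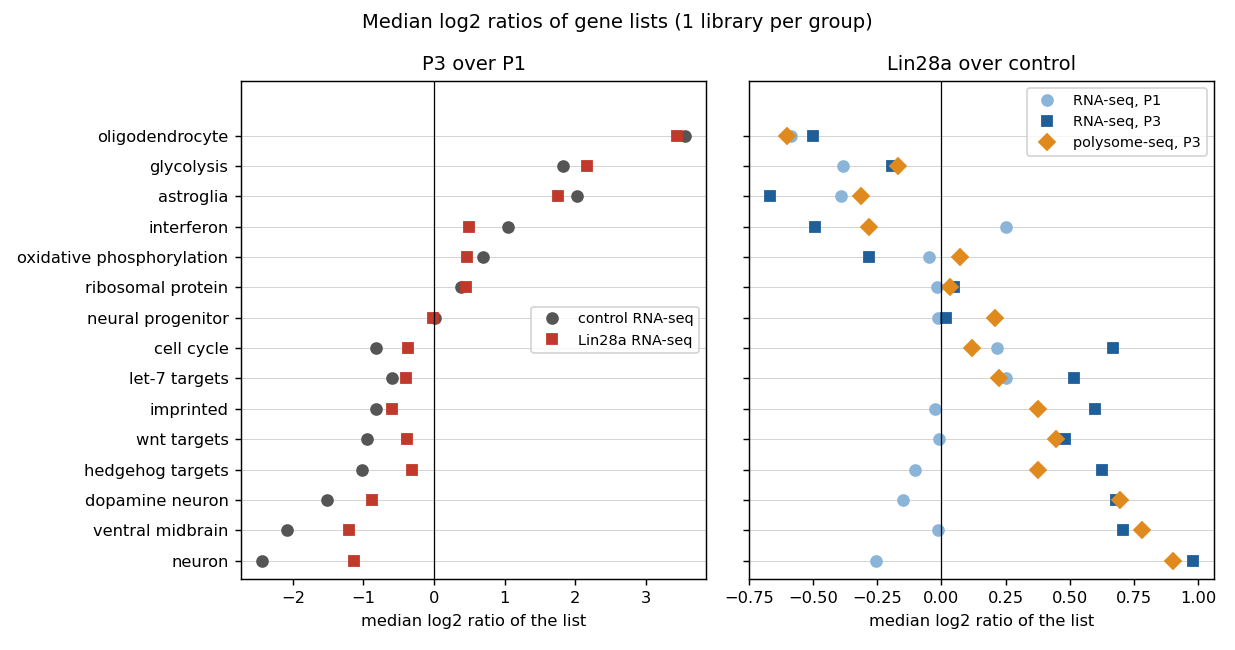
Median log2 ratio of each gene list (points), for P3 over P1 in control and Lin28a RNA-seq on the left and for Lin28a over control in RNA-seq at P1, RNA-seq at P3 and polysome-seq at P3 on the right, with 1 library per group. Neuronal genes sit at -2.43 and -1.14 on the left, and at -0.25, 0.98 and 0.90 on the right.

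At P1 the Lin28a culture differed little from control apart from a small set of genes. Hmga2 and Igf2bp1, both known let-7 targets, were higher, with log2 ratios of 1.62 and 1.21 (14.6 against 4.10 FPKM and 23.4 against 9.53 FPKM). The 27 measured let-7 targets had a median of 0.25, with 2 higher past 2-fold, 25 within and the random range ending at 0.08. Cell cycle genes were slightly higher in 39 of 40 cases with none past 2-fold (median 0.22; Tk1 0.62, Cdc6 0.49). Genes of cell cycle inhibition and the p53 response were also above the random range, higher by any amount in 19 of 29 cases and 1 past 2-fold (median 0.20; Cdkn1a 1.04). Glial genes were lower without passing 2-fold, 22 of 26 astroglial genes (median -0.39; Mt3 -0.91) and 12 of 13 oligodendrocyte genes (median -0.59; Pdgfra -0.95, Sox10 -0.80). Glycolysis genes were lower by any amount in 20 of 22 cases, only Pdk1 (-1.08) past 2-fold (median -0.38). Neuronal genes were lower in 26 of 28 cases, again within 2-fold (median -0.25; Mapt -0.62, Gap43 -0.48). The dopamine neuron list was just below the random range (median -0.15, percentile 1.91), and the ventral midbrain list lay inside it (-0.01). In total 17 genes were higher and 12 lower among 12564, counts that became 43 and 46 with a pseudocount of 0.1. The counts include Hnrnpd, listed at the floor in Lin28a, and the near-identical copies Tmem254b and Tmem254c, whose ratios are uncertain. These lists were at most modestly displaced, and with 1 library each a shift of this size cannot be set against culture to culture variation.

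At P3 Lin28a cultures had higher neuronal, midbrain and proliferation genes than control, and lower glial genes. Neuronal genes were higher in 24 of 25 cases, 12 past 2-fold (median 0.98), with Nhlh2 at 2.23, Syt4 at 2.19, Tubb3 at 2.08 and Dcx at 1.73. Ventral midbrain genes were higher past 2-fold in 7 of 19 cases (median 0.71; Lmx1b 1.64, Lmx1a 1.44, Foxa2 1.34), and 4 of 12 dopamine neuron genes were (median 0.68), among them tyrosine hydroxylase, Th (1.06). Let-7 targets were higher past 2-fold in 6 of 26 cases with none lower (median 0.52), with Igf2bp1 at 1.68, Tgfbr1 at 1.48, Hmga2 at 1.46 and Igf2bp2 at 1.37. Cell cycle genes had a median of 0.67 with 35 of 40 higher and none past 2-fold (Plk1 0.89, Bub1b 0.89). Astroglial genes were lower past 2-fold in 9 of 29 cases (median -0.67; Gfap -2.46, Mt3 -1.67, Aqp4 -1.59). All 19 oligodendrocyte genes were lower, 2 past 2-fold (median -0.50; Opalin -1.78, Olig1 -1.10). Oxidative phosphorylation genes were lower in 75 of 76 cases, all within 2-fold (median -0.28), and antioxidant genes in 29 of 32, 2 past 2-fold (median -0.41; Mt2 -1.85, Mt1 -1.47). Glycolysis (median -0.19) and the p53 response (-0.07) lay inside the random range, although Igfbp3 (-1.56) and Cdkn2b (-1.23) were lower. In total 166 genes were higher and 171 lower among 12716, or 343 and 333 with a pseudocount of 0.1.

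The Lin28a effects at P1 and P3, which share no library, correlated across 12142 genes at a Pearson r of 0.316 and a Spearman rho of 0.353, and 63.0% of genes had the same sign. Past 2-fold, 8 genes were higher and 2 lower at both passages, where independent lists would share 0.183 and 0.0927. With 1 short non-coding gene left out, the 7 higher genes were Lin28a, Hmga2, Igf2bp1, Snurf (2.71 at P1, 4.14 at P3), the chemokine Cxcl1 (1.39, 1.48), Tmem254c (2.96, 1.20) and the pseudogene Apoo-ps (1.04, 1.37). The 2 lower genes were Ramp1 (-1.23, -1.16), a receptor-modifying protein, and Tmem254b (-2.13, -1.14). Tmem254b and Tmem254c are near-identical copies whose reads may be split between them, so their opposite ratios are uncertain. Snurf overlaps Snrpn in 1 transcript, and in polysome-seq it was at 43.8 RPKM in control and 49.3 in Lin28a, so its ratio is uncertain as well. Cxcl1 was low at P1, with 0.124 FPKM in control and 1.94 in Lin28a. In polysome-seq Cxcl1 went the other way, with 17.6 RPKM in control and 10.6 in Lin28a.

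The gene ratios of passage in control and of Lin28a at P3 were opposed, but both use the P3 control library. Their Pearson r was -0.725 and their covariance -0.283 over 12646 genes, where unchanged libraries sharing that control gave -0.499 and -0.0347. The simulated r is fixed by equal noise without any passage effect, so -0.725 cannot be read against it. The simulated covariance holds for the assumed noise only. The polysome libraries offer a comparison with no library in common. Across 12039 genes the passage ratios in control correlated with the polysome ratios of Lin28a to control at a Pearson r of -0.622 and a Spearman rho of -0.537. The Lin28a ratios at P3 in RNA-seq and in polysome-seq correlated at 0.522 and 0.449.

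In polysome RNA at P3, genes lower with passage in control were mostly higher with Lin28a, but few of them past 2-fold. P3 control cells shared by both assays could add to this opposition. The 873 measured genes lower at P3 in control had a median polysome log2 ratio of 0.44, and 818 of them were higher in Lin28a by any amount; random lists ranged from 0.03 to 0.06. The 1307 genes higher at P3 had a median of -0.22 with 1044 lower by any amount, against random lists of 0.07 to 0.10. Past 2-fold both ways there were 103 genes lower with passage and higher in Lin28a polysomes (8.27 if independent). The leading ones were the proneural factor Neurog2 (-5.06 with passage, 2.68 in polysomes), Tubb3 (-3.96, 2.27), Dlx1os (-3.18, 2.11), Vat1l (-3.33, 1.99), Nhlh2 (-4.66, 1.95), Chgb (-2.09, 1.90), Igdcc3 (-1.93, 1.87), Dbx1 (-5.05, 1.77), Ly6h (-2.87, 1.76) and Nhlh1 (-3.64, 1.66). The other way there were 14 genes (1.63 if independent), led by Ramp1 (3.37, -1.43), 2010001M06Rik (1.86, -1.22), Camk2b (2.16, -1.19), the integrin Itga7 (4.12, -1.15), the peptide hormone gene Adm (3.10, -1.13), Lpo (2.39, -1.13), Apobec1 (3.94, -1.12), Mt2 (4.67, -1.09), the neurotrophin receptor Ntrk2 (3.67, -1.07) and Dbx2 (3.47, -1.07).

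**Figure D2:**
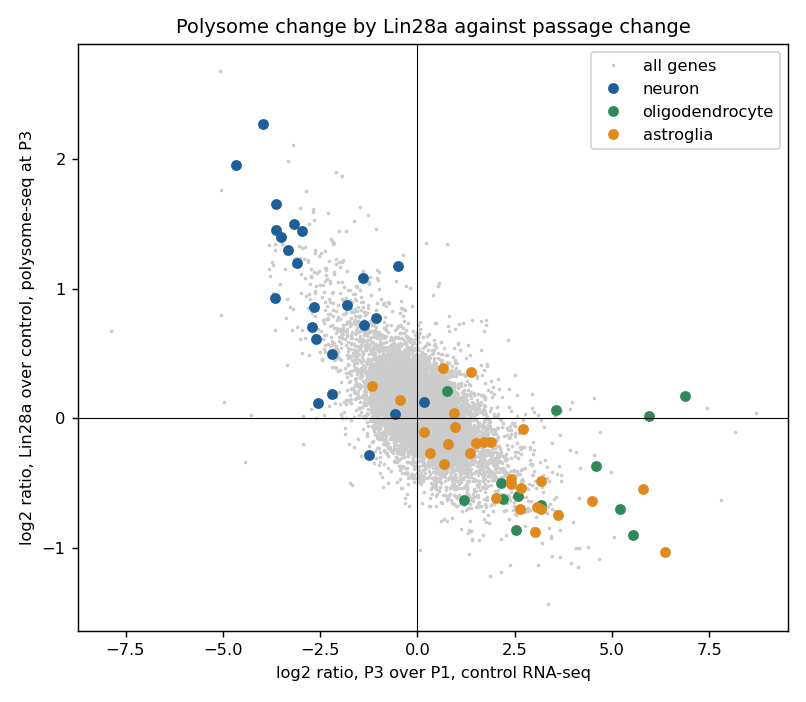
Each point is a gene, with its log2 ratio of P3 over P1 in control RNA-seq on the horizontal axis and its log2 ratio of Lin28a over control in polysome-seq at P3 on the vertical axis; neuronal, oligodendrocyte and astroglial genes are coloured. The axes share no library but may share P3 control cells, and the Pearson r across 12039 genes was -0.622.

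In the polysome comparison as a whole, 117 genes were higher and 15 lower with Lin28a among 12289, or 249 and 61 with a pseudocount of 0.1. The 9 highest genes after Lin28a and the 10 lowest were those just named. Neuronal genes were higher in 23 of 24 cases, 11 past 2-fold (median 0.90; Tubb3, Nhlh2, Nhlh1, and Stmn2 at 1.502). Ventral midbrain genes were higher past 2-fold in 8 of 21 cases (median 0.78; Slit2 1.34, Shh 1.34, Lmx1a 1.28), and 3 of 10 dopamine neuron genes were (median 0.70; Dlk1 1.53). Let-7 targets were higher past 2-fold in 4 of 29 cases (median 0.22; Hmga2 1.46, Igf2bp1 1.37, Mycn 1.17, Plagl2 1.04). Astroglial genes were lower by any amount in 23 of 28 cases, 1 past 2-fold (median -0.31; Gfap -1.03), and oligodendrocyte genes in 9 of 13, none past 2-fold (median -0.60; Bcas1 -0.90). Genes of the cell cycle (0.12), oxidative phosphorylation (0.07), ribosomal proteins (0.03) and translation factors (0.06) lay inside the random range. Below it, with few or no members past 2-fold, were cell cycle inhibition and the p53 response (-0.20, 21 of 28 lower by any amount), glycolysis (-0.17, 15 of 22) and antioxidant genes (-0.06, 19 of 31). Immediate early genes, which respond to the handling of cells, were lower by any amount in 17 of 19 cases in the polysomes of Lin28a, none past 2-fold (median -0.37; Fos -0.81), and in 7 of 7 for the polysome to RNA ratio (-0.27). In RNA-seq at P3 their median was -0.16, inside the range.

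Polysome and RNA-seq levels for the same virus and passage differed in kind. The sources used here do not say whether both assays used the same cells. In control, Mbp was at 633 FPKM in P3 RNA-seq and 1.51 RPKM in polysomes, Gapdh at 3284 and 32.4, and the ribosomal protein gene Rpl3 at 1367 and 52.6. RNAs that lack a poly(A) tail went the other way, with the histone gene Hist1h4d at 1.11 FPKM and 1681 RPKM and the RNase MRP gene Rmrp at 0.954 and 8850, and the nuclear RNA Malat1 was at 87.6 and 968. All genes of this paragraph were chosen after their polysome values were seen. The polysome control library correlated with P3 control RNA-seq and with P1 control RNA-seq at 0.890 each. The polysome Lin28a library correlated at 0.897 with P3 Lin28a and at 0.907 with P1 Lin28a RNA-seq.

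The change in the polysome to RNA ratio between Lin28a and control was small for most of 7817 genes, with 28 higher and 4 lower and a median of 0.07. With that median removed the counts were 20 and 13. These ratios assume that both assays drew on like P3 cells. That is not known, and it is taken up below for oligodendrocyte genes. The highest included Rps27 (2.61), Dhrs1 (1.78), Crip1 (1.42), the growth factor Mdk (1.36), the histone gene Hist1h2bc (1.36), S100a4 (1.27), Id4 (1.24), the linker histone gene Hist1h1c (1.22) and Id2 (1.22). For Rps27 the ratio came from RNA-seq, with 152 FPKM in control and 25.6 in Lin28a against 17.0 and 18.1 RPKM in polysomes. At P1 Rps27 was at 28.7 FPKM in control and 37.7 in Lin28a, so the P3 control value alone stood apart. For Mdk the ratio came from polysomes, with 30.3 and 79.0 RPKM against 207 and 205 FPKM. The lowest were Dab1 (-1.12), the growth factor receptor Egfr (-1.08), the spindle gene Aspm (-1.01), Elavl4 (-1.01), Ccnf (-0.99), C330027C09Rik (-0.97), Ckap2l (-0.97), Arhgef39 (-0.96), the Argonaute gene Ago2 (-0.95) and the kinetochore gene Cenpf (-0.95). Cell cycle genes had lower ratios by any amount in 29 of 33 cases (median -0.54; Mki67 -0.92, Bub1b -0.89), and let-7 targets in 15 of 18 (median -0.21; Igf2bp2 -0.65, Dicer1 -0.59). Oxidative phosphorylation genes had higher ratios in 73 of 76 cases (median 0.34; Ndufa4 0.80), as did 24 of 27 antioxidant genes (median 0.43; Gsta4 0.76) and 46 of 48 genes of the secretory pathway (median 0.27; Sdf2l1 0.94), and no member of these 5 lists passed 2-fold. Neuronal genes (0.19, 9 of 30 members measured) and ventral midbrain genes (0.24, 10 of 26) lay inside the random range. So did dopamine neuron genes (0.17, 4 of 21) and oligodendrocyte genes (0.16, 5 of 20). With so few members measured, their ratios cannot be called unchanged. Astroglial genes were above the random range (0.32). Ribosomal proteins (median 0.01) and translation factors (0.01) were below a range that was itself shifted up. Both medians became -0.06 with the median gene removed. Between Lin28a and control at P3, cell cycle and let-7 target medians were 0.67 and 0.52 in RNA-seq and 0.12 and 0.22 in polysomes. Oxidative phosphorylation, antioxidant and secretory pathway genes were at -0.28, -0.41 and -0.20 in RNA-seq and 0.07, -0.06 and 0.08 in polysomes. The ratios of these lists thus came mainly from RNA-seq. These medians also cover members below the minimum of 5.

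Small RNA-seq showed the let-7 guide strands far lower with Lin28a at P3. The 9 let-7 and miR-98 guides took 5.52% of microRNA counts in P1 control and 12.5% in P3 control. In Lin28a they took 4.51% at P1 and 2.97% at P3. These are shares of counts, in which guides with several loci, such as let-7a-5p, may be counted more than once. At P3 all 9 guides were lower, 8 past 2-fold, with a median log2 ratio of -2.91. The count ratios of Lin28a to control were 0.0970 for miR-98-5p (0.0934 to 0.101), 0.104 for let-7i-5p (0.102 to 0.105), 0.105 for let-7d-5p (0.101 to 0.108), 0.117 for let-7f-5p (0.115 to 0.118), 0.133 for let-7b-5p (0.130 to 0.136) and 0.135 for let-7a-5p (0.133 to 0.137). They were 0.192 for let-7g-5p (0.188 to 0.197), 0.249 for let-7e-5p (0.242 to 0.257) and 0.509 for let-7c-5p (0.506 to 0.512). At P1 the family median was -0.47 with no guide past 2-fold. The ratios there ran from 0.550 for let-7b-5p to 1.09 for let-7c-5p. At that passage let-7c-5p (log2 0.13) and let-7e-5p (0.09) were higher than in control, and both were lower (-0.04 and -0.08) once the median microRNA was centred.

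From P1 to P3 the guides were higher in control and lower in Lin28a. In control all 9 were higher, 6 past 2-fold (median 1.13), with let-7b-5p at 2.94. In Lin28a 7 were lower past 2-fold (median -1.44), while let-7b-5p (0.90) and let-7c-5p (0.29) were higher within 2-fold. Let-7 precursors differ in a motif bound by the cold-shock domain of Lin28. The 5 guides from precursors with it had a median of -3.26 for Lin28a against control at P3 and the 3 from precursors without it -2.003, and at P1 the medians were -0.50 and 0.09. The classes overlapped at P3, with let-7a-5p of the class without it at -2.89 and let-7g-5p of the class with it at -2.38. Let-7f-5p, made from precursors of both kinds, was left out of both. The microRNAs made from the same primary transcripts as some let-7 genes, such as miR-100-5p and miR-125b-5p, were all within 2-fold in both Lin28a comparisons (medians -0.41 at P1 and 0.51 at P3, inside the random range).

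**Figure D3:**
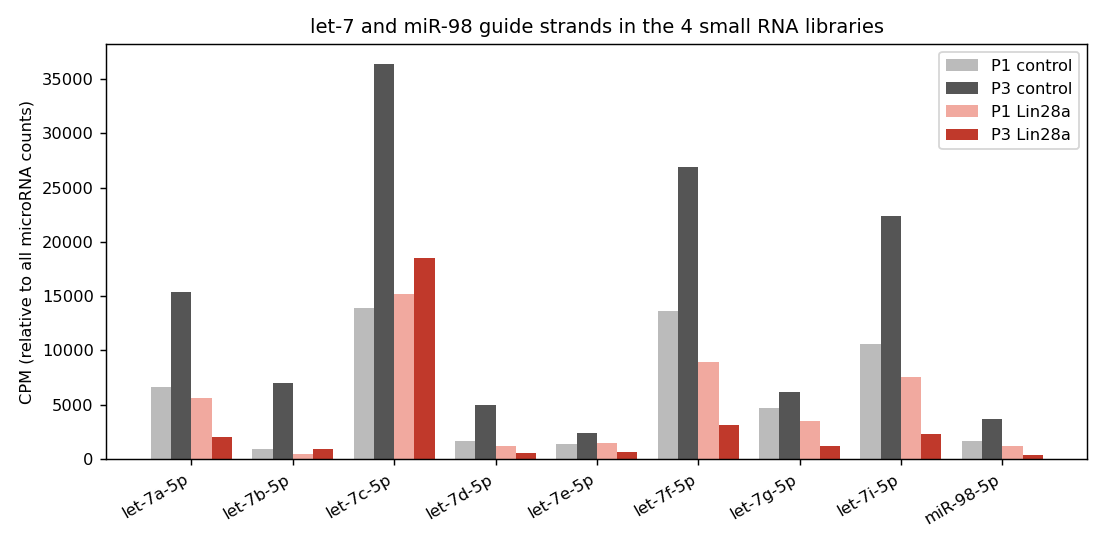
Share of microRNA counts, in CPM, of each let-7 and miR-98 guide strand (bars from 0) in the 4 small RNA libraries, 1 library per bar. Together they took 12.5% of counts in P3 control and 2.97% in P3 Lin28a.

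Other microRNAs also changed with passage, and a link to the cell type genes was not tested. Of 17 neural microRNAs 6 were higher and 8 lower in control (median -0.21, inside the random range). In Lin28a 4 were higher and 8 lower (median -0.60, just below the range). The 10 highest at P3 in both cultures were miR-184-3p (log2 4.86 in control, 4.89 in Lin28a), the hypoxia-induced miR-210-3p (4.18, 3.64) and miR-210-5p (3.31, 4.17), miR-8115 (3.65, 3.38), miR-3093-5p (3.10, 3.64) and miR-3093-3p (3.34, 3.25), the oligodendrocyte microRNAs miR-219a-2-3p (3.47, 3.12) and miR-338-5p (4.17, 2.102), miR-9-3p (2.71, 3.03) and miR-21a-3p (3.84, 2.44). The lowest were miR-708-3p (-3.60, -2.92), miR-10b-5p (-3.71, -2.79), miR-135b-3p (-3.85, -2.33) and miR-135b-5p (-3.59, -2.33), miR-592-5p (-3.42, -2.28), miR-218-5p (-2.22, -2.19), the neuronal miR-124-3p (-3.18, -2.06), miR-873a-5p (-2.61, -2.06), miR-224-5p (-3.32, -1.96) and miR-135a-2-3p (-2.80, -1.86). In control 116 microRNAs were higher and 124 lower among 428, and in Lin28a 55 and 75 among 424. The median microRNA in Lin28a was at -0.11, and with it removed the counts were 68 and 56. Scaling without let-7 removed a shift of -0.11 in control, so ratios there were higher. Passage ratios of the 2 cultures correlated at a Pearson r of 0.761 and a Spearman rho of 0.731 across 414 microRNAs, with 43 higher and 50 lower in both (14.2 and 20.9 if independent).

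Between Lin28a and control, 11 microRNAs were higher and 18 lower at P1 among 414. The median microRNA there was at 0.17, and with it removed the counts were 8 and 28. At P3 64 were higher and 50 lower among 414, or 52 and 61 when the libraries were scaled without let-7, which removed a shift of 0.16 and lowered the ratios. The effects at the 2 passages correlated at a Pearson r of only 0.169 and a Spearman rho of 0.0690 across 390 microRNAs. Past 2-fold at both, 5 were higher (1.62 if independent), namely miR-154-3p (log2 1.45 at P1, 1.39 at P3), miR-341-3p (1.23, 1.28), miR-485-3p (1.20, 1.76), miR-376b-3p (1.14, 1.11) and miR-1251-5p (1.32, 1.06), and 3 were lower (1.76 if independent), namely miR-19b-3p (-2.07, -1.69), miR-98-3p (-1.66, -1.88) and miR-145a-5p (-1.19, -1.03). MicroRNAs of the imprinted Dlk1-Meg3 cluster were higher past 2-fold in 4 of 34 cases at P1 (median 0.56) and in 22 of 34 at P3 (median 1.24; miR-431-5p 2.37, miR-411-5p 2.16, miR-369-5p 2.14), none lower. In control 26 of 34 were lower at P3 than at P1 (median -1.60), and in Lin28a 5 of 34 (median -0.77). Neural microRNAs at P3 had 2 of 17 higher and 2 lower (median 0.43, inside the range), with miR-124-3p at 1.59 and miR-338-3p at -1.13. None of 12 microRNAs typical of pluripotent cells reached 10 CPM.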

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

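The tests of this part were all chosen only after the result was seen. Neuronal genes drew attention because Lin28a moved them opposite ways at the 2 passages, with a list median of -0.25 at P1 and 0.98 at P3, and dopamine neuron genes did likewise (-0.15 and 0.68). These differences between passages were not tested, since each group held 1 library. An unusual P3 control RNA-seq library is argued against by the polysome pair, which does not use it and gave a median of 0.90, although both assays may share an unusual culture. A delay of the Lin28a culture along the passage changes stays open: the passage median in Lin28a was 0.468 times that in control for neuronal genes (bootstrap over genes 0.401 to 0.615), 0.588 for ventral midbrain genes (0.492 to 0.837) and 0.457 for the cell cycle (0.252 to 0.931). It was 0.867 for astroglia (0.628 to 1.20), 0.894 for oligodendrocyte genes (0.829 to 1.13) and 1.19 for glycolysis (0.963 to 1.29). These ranges lay above that of neuronal genes, but only glycolysis also lay above those of ventral midbrain and the cell cycle. The glycolysis ratio cannot decide against a uniform delay, because the median of these genes in Lin28a was below control already at P1 (-0.38). A low start can raise the ratio, and at P3 their median was -0.19, inside the random range. Oxidative phosphorylation genes, at 0.675 (0.598 to 0.745), go with a delay. All these lists but ventral midbrain already differed at P1. Ranges over genes do not cover variation between cultures. A larger share of neurons in the Lin28a culture at P3 stays open and was not decided: 24 of 25 neuronal genes were higher in RNA-seq and 23 of 24 in polysomes, but the list medians had already fixed that most would be.

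The other results drew attention because 2 groups moved in opposite directions, and none of these differences was tested. Interferon genes had a median Lin28a effect of 0.25 at P1 and -0.49 at P3. The Lin28a effect on miR-10a-5p was -1.18 at P1 and 1.52 at P3, and that on miR-377-3p was -1.07 and 1.06. The passage effect on the let-7 family had a median of 1.13 in control and -1.44 in Lin28a. It was 1.21 and -1.44 for let-7a-5p, 1.57 and -1.19 for let-7d-5p, 1.08 and -1.69 for let-7i-5p, 1.33 and -1.27 for let-7i-3p, and 1.13 and -1.77 for miR-98-5p. The passage effect on Amd1 was 3.92 in control and -1.20 in Lin28a. Its P1 and P3 values were 0.560 and 22.6 FPKM in control and 1.33 and 0.0147 FPKM in Lin28a. The polysome libraries had 15.7 RPKM in control and 16.5 in Lin28a, far from 0.0147 FPKM, so the RNA-seq ratio in Lin28a is uncertain. The passage effect on Hnrnpd was -1.52 in control, from 63.2 to 21.4 FPKM. In Lin28a Hnrnpd was listed at the floor at P1 and at 26.8 FPKM at P3, so its value of 4.80 on the log2 scale with pseudocount is no measured fold. In polysomes Hnrnpd was at 8.52 and 10.0 RPKM.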

How the results depend on the processing

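No paired analysis was possible within a comparison because each group held a single library. Treating the 2 passages as pairs was not done. Of 102 values of counts and agreements under the alternatives, 74 stayed within their limits and 28 moved. Of 238 values of named genes 226 were unchanged in call and 12 passed 2-fold only under an alternative, and of 709 values of lists 687 were unchanged, 13 fell back inside the random range or weakened, 4 became stronger and 5 changed sign.

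With a pseudocount of 0.1, which lets low genes pass 2-fold, the Lin28a effect had 43 genes higher and 46 lower at P1 and 343 and 333 at P3. Passage in Lin28a had 966 lower, polysomes 249 higher and 61 lower, and the polysome to RNA ratio 11 lower. The correlation of Lin28a effects was then 0.254 and that of passage effects 0.886. With a minimum of 5, which leaves fewer genes, 9 genes were higher at P1 and 108 at P3 with Lin28a, and the correlations were 0.377 and 0.916. Forebrain genes (-0.0151) and Hedgehog targets (-0.19) then changed sign at P3. The polysome to RNA ratio had 68 genes higher and 13 lower with a minimum of 1, 16 and 2 with a minimum of 10, and 13 lower when centred on the median gene. Centring turned ribosomal proteins to -0.0609 and translation factors to -0.0610, by construction. For small RNA, a minimum of 100 CPM left fewer microRNAs. The Lin28a effect then had 5 higher and 11 lower at P1 and 29 higher at P3, and passage 67 and 65 in control and 30 and 38 in Lin28a. Neural microRNAs at P1 turned to 0.10. With no minimum 27 were higher at P1, and with the median centred 28 were lower. Where no construction is named, the cause was not tested. In polysomes, the genes lower and those higher with passage in control kept their opposite medians under the alternatives run for them, the pseudocount of 0.1, the minimum of 5 and centring.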

Other observations

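Imprinted genes, many of which regulate growth, had lower medians at P3 than at P1 in both cultures. In control 10 of 22 were lower at P3 than at P1 (median -0.83; Meg3 -2.26), and in Lin28a 7 were lower and 2 higher (median -0.60; Mest -1.67, H19 2.09). With Lin28a against control at P3, 7 of 22 were higher and none lower in RNA-seq (median 0.60; Igf2 1.53, Meg3 1.48, H19 1.45), and 3 of 22 in polysomes (median 0.37; Nnat 1.26, Cdkn1c 1.02). At P1 their median was -0.03, inside the random range. Targets of Wnt and Hedgehog signalling, which pattern the midbrain, were lower with passage in control (6 of 15, median -0.95, Lef1 -3.48; 6 of 11, median -1.02, Gli1 -2.39). In Lin28a the medians were -0.38 for Wnt, below the random range, and -0.31 for Hedgehog, inside it. With Lin28a at P3 their medians were 0.48 and 0.63 in RNA-seq, with 2 of 15 and 0 of 10 higher past 2-fold (Lef1 1.32), although Hedgehog targets turned lower (-0.19) among genes at 5 FPKM or more. In polysomes their medians were 0.44 and 0.38. Targets of BMP and TGF-beta had a median of -0.27 in RNA-seq (Id2 -0.73) and of 0.40 in polysomes (Id4 1.13).

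Interferon genes were higher with passage in 11 of 16 cases in control (median 1.05; Tap1 2.15, Psmb8 1.90) and in 1 of 16 in Lin28a (0.49). Genes of small RNA processing were higher by any amount in all 17 cases with Lin28a at P3, 2 past 2-fold (median 0.29; Ago2 1.26, Dicer1 1.04) and lower with passage in control (-0.57). Extracellular matrix genes were higher with passage in 14 of 38 cases in control and 13 in Lin28a (medians 0.66 and 0.50; Itga7 4.12 in control). Forebrain genes, which mark another region, were lower with passage in both cultures (-1.07 and -1.13; Dlx1 -3.01 in control), and their median at P3 with Lin28a was 0.42, turning to -0.02 among genes at 5 FPKM or more. Within the miR-17-92 family, miR-19a-3p was lower with Lin28a (-2.14 at P1, -0.89 at P3), as was miR-19b-3p (-2.07, -1.69). The other members were spread, with miR-92a-3p at 1.02 and -0.52 and miR-18a-5p at 0.27 and -1.54.

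The tests on polysomes and let-7c were chosen only after the result was seen, apart from the one on cells with less passage change, whose wording and criteria were narrowed later. Oligodendrocyte genes were low in the P3 polysome libraries, with a median log2 polysome to RNA ratio of -3.95 in control (0.19 against P1 RNA-seq). Matched random lists ran from -1.61 to -0.52, which argues against a shift common to genes of that RNA level. Losses particular to some genes are not excluded, since ribosomal protein genes also lay below their range (-4.07, and -3.67 against P1 RNA-seq). Glycolysis genes lay below theirs (-2.72) but were at -0.75 against P1 RNA-seq, so cells with less passage change could also give that. Polysome RNA from cells with less passage change cannot be told: genes lower at P3 in both cultures had a high ratio (0.36), as had the 482 chosen in the Lin28a culture alone, without the P3 control library (0.35, random lists -0.27 to -0.10), and cell cycle genes (0.15). Genes higher in both (-1.64) and astroglial genes (-2.26) were low, but neuronal genes (-0.88), also lower with passage, lay inside their range. Fewer oligodendrocyte lineage cells in the cells used for polysomes stay open and were not decided: 17 of 19 genes lay below the median of all genes, but the list median had already fixed that most would. Low ribosome loading and such losses also stay open.

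Let-7c-5p was lowered least of the guides by Lin28a at P3, and the lower end of its exact interval, 0.506, argues against counting noise, as the 8 others ran from -3.36 to -2.003 on the log2 scale. Reads from the let-7c-2 hairpin, if spared by Lin28a, could explain it, since its 3p arm was at -0.87 and that of let-7c-1 at -2.73. The 3p arm of let-7c-2 has the same sequence and counts as that of let-7a-1, so this stays open.

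A hypoxia-like response at P3 was an added hypothesis, drawn from glycolysis genes and miR-210, and its test was written before its list was run. The list of 20 hypoxia-induced genes outside glycolysis left out Adm and Ndufa4l2, which had been seen. Its median passage ratio was 1.69 in control, with 16 of 20 genes higher, and 1.79 in Lin28a, with 18 higher (Bnip3 3.17 and 4.16, Vegfa 2.95 and 2.90). That fits a hypoxia-like response in both cultures. The cultures differed in this list already at P1 (median of Lin28a against control -0.42, below the random range) and in polysomes at P3 (-0.18, below it), while RNA-seq at P3 lay inside (-0.23). Oxygen and culture density are not given in the sources used here, and other regulators of these genes stay open.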
